A study of Mus musculus with 2 samples.

How the data were processed

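Expression was measured on 2 Affymetrix whole-transcript mouse arrays, 1 for mouse embryonic fibroblasts given DMSO and 1 for the same kind of cells given celastrol. Total RNA was extracted with Trizol and cleaned on a column, and biotin-labelled with the Ambion WT expression and terminal labelling kits, per the labels' protocols. The deposited values are on a log2 scale and were made by the authors with RMA (robust multi-array average: background correction, quantile normalization of probes and a summary per probe set), as the submitters' processing notes name that tool. Its version, the settings, and whether other arrays entered the same normalization are not given in the sources used here. The log2 base was taken from the values, which ran from 2.73 to 14.5 over both arrays with medians of 6.33 and 6.35, as RMA gives, and were not centred per gene. The columns carried the sample identifiers, so no column had to be assigned by its order or values, and 0 other columns of values were present. RMA tends to compress differences of dim probe sets, so a fold change of a gene near background is understated. Scanner files were not used here, so background, saturation and hybridisation quality of each array could not be examined.

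The table held 35556 probe sets. GEO's platform annotation named exactly 1 gene for 21797 of them, several genes for 1613 and none for 12146, which include the array's control probes. Probe sets naming several genes or none entered no comparison. Entrez identifiers of 21698 of the 21797 probe sets were found in a mouse gene table for GRCm38.p6, used for names only, and the other 99 kept the annotation's symbol. The value of a gene was that of its probe set with the highest mean over both arrays, which concerned 999 of the 19946 genes, the rest having 1 probe set. A gene counted as detected if its value in at least 1 array exceeded 5.73, the 95th percentile of 1210 probe sets for olfactory and vomeronasal receptors, which fibroblasts are not expected to express. This left 13902 genes.

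The difference was the celastrol value minus the DMSO value on the log2 scale. With 1 array per group there is no estimate of the spread between cultures, so no p-value, standard error or interval was computed, and each difference has no replicate check. The number of arrays limits the precision. For 3 of the named genes the DMSO value lay under the detection limit, and their fold is given as a lower bound against that limit. Fold sizes are 2 raised to the log2 difference.

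29 gene lists (23 pathways, complexes or transcription factor target sets and 6 sets of markers of other cell types) were fixed before the data were examined, as were the detection limit, the named-gene rule and the alternatives. For each list the median difference of its detected members was set against the medians of 10000 random lists of the same size, drawn from genes off the list and matched on mean expression in 20 bins. A list is called apart when its median lay outside the central 95% of the random medians. Chance alone would set 1.45 of 29 lists apart, so the lists that also passed a limit divided by 29 (a tail of 0.0862% on each side) are named. Co-regulated members would set more lists apart. The divided limit does not allow for this, because the random lists are drawn gene by gene. This percentile describes these 2 arrays and is no test of the compound. 10 genes belonged to 2 lists. On simulated data for this comparison (13902 genes, differences shuffled within expression bins, 580 simulated lists per size) the procedure set 4.31% of unchanged lists apart, and called 71.4% of lists shifted by 0.2 and 99.5% of lists shifted by 0.5 on the log2 scale. Shuffling removes co-regulation, and the shift was the same for all members, so these shares do not apply to co-regulated lists.

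The genes named by rule are the 12 detected genes with the largest difference in each direction, leaving out provisional symbols, receptor genes and small RNAs, together with up to 2 members in each direction from each list and the 3 brightest members of each marker list, 119 genes in all. Some genes outside this rule are also named, as limits on a result or in the closing observations. Alternatives were another detection limit (the median of all probe sets) or none, the mean of a gene's probe sets, quantile normalization of the 2 arrays, subtraction of a lowess trend (fraction 0.3) or of the median difference, fold thresholds of 1.5 and 3 in place of 2, random lists not matched on expression, and a trimmed mean (10% from each end). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.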

Results

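Mouse embryonic fibroblasts, connective tissue cells grown from embryos, were infected with an adenovirus carrying LacZ, a bacterial enzyme gene commonly used as a control cargo. They were then given either DMSO, the solvent, or 250 nM celastrol for 7 h in medium with 1% serum. Celastrol is a triterpenoid quinone methide from the thunder god vine. Transcript levels were measured on 1 array per condition, so the design asks which transcripts differed between the treated and the solvent culture and contains no replicate. Of 35556 probe sets, 60.5% lay above the detection limit in the DMSO array and 60.9% in the celastrol array. Values of the arrays correlated across probe sets (Pearson r = 0.988), a figure over genes, which are not independent replicates.

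The largest positive differences included genes of glutathione and haem metabolism, a heat shock gene and circadian repressors, and the largest negative ones included inflammatory and sterol synthesis genes. Of 13902 detected genes, 262 were at least 2-fold higher with celastrol and 92 at least 2-fold lower, and 13548 lay between. Differences of at least 4-fold were seen for 19 genes upward and 3 downward. The highest value was that of Slc7a11, the cystine transporter subunit (probe set 10498024), at 7.92 with DMSO and 11.08 with celastrol, an 8.90-fold difference. Hmox1, which encodes the inducible haem oxygenase (probe set 10572897), was 8.04-fold higher, and Chac1, a glutathione-degrading enzyme, was 5.81-fold higher. Gsta4, a glutathione transferase, was 5.62-fold higher. Ifi203, of the interferon-inducible p200 family, was 7.74-fold higher, a value left uncertain by the close similarity of that family's genes. Dusp4, a MAP kinase phosphatase, was 6.23-fold higher. Ciart, Bhlhe41 and Nr1d1, 3 transcriptional repressors of the circadian clock, were 6.14-fold, 5.18-fold and 4.96-fold higher, and the second probe set of Ciart also gave a positive difference (2.27 on the log2 scale). Gml, a GPI-anchored protein gene, and Car6, a secreted carbonic anhydrase, were under the detection limit with DMSO, and their values with celastrol were at least 4.06-fold and at least 4.96-fold higher. Hspa1a, a stress-inducible HSP70 gene, was 5.01-fold higher, a value that its near-identical copy Hspa1b leaves uncertain.

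In the other direction, Nos2, the inducible nitric oxide synthase (probe set 10379228), had the lowest difference, at 9.99 with DMSO and 7.48 with celastrol, 5.69-fold lower. Steap4, a metalloreductase, was 4.65-fold lower and Cxcl5, a neutrophil chemokine, 4.19-fold lower. Hmgcs1 and Idi1, enzymes of the mevalonate pathway, were 3.74-fold and 3.32-fold lower. Vcam1, a leukocyte adhesion molecule, was 3.54-fold lower. Tgfb3, a TGF-beta ligand, was 3.33-fold lower, and Angpt1, an angiopoietin, and Has2, a hyaluronan synthase, were 3.20-fold and 3.17-fold lower. Pcdh18, a protocadherin, was 3.29-fold lower, Atoh8, a bHLH transcription factor, 3.23-fold lower, and Wdr6, a WD-repeat protein gene, 3.22-fold lower.

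As a measure of technical scatter within these 2 arrays, the central 95% of the 1210 receptor probe sets differed by between -0.42 and 0.41 on the log2 scale. At least 2-fold higher values were seen for 2 of them (0.165%) against 1.88% of the detected genes, and none was 2-fold lower. Receptor probe sets are dim, RMA tends to compress their differences, and their scatter does not contain the variation between cultures. Their share is therefore no noise rate for the detected genes. Of the 12146 probe sets without a gene name, 202 were higher and 216 lower by at least 2-fold, counted without a detection limit. For the 761 genes with several detected probe sets, the probe sets of a gene differed by a median of 0.10 in their log2 difference, and by up to 0.51 for 90% of these genes.

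**Figure D1:**
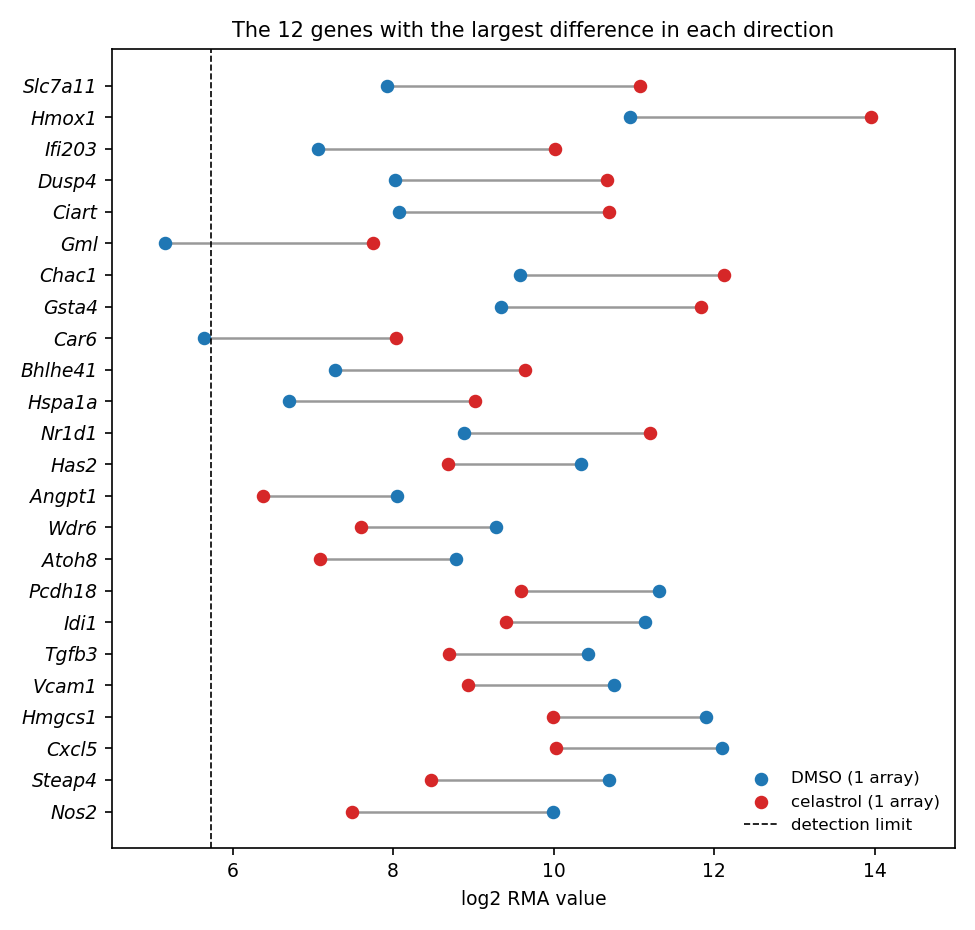
Log2 RMA value (x axis) of the 12 genes with the largest positive and the 12 with the largest negative difference (y axis), with 1 DMSO array (blue) and 1 celastrol array (red) per gene and the detection limit dashed at 5.73. Only Gml and Car6 start under the limit, and the differences run from -2.51 for Nos2 to 3.15 for Slc7a11.

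Genes of 3 stress programmes were higher with celastrol. All 24 detected members of the heat shock list had higher values with celastrol, 12 of them by at least 2-fold. The list holds mainly cytosolic chaperones and their partners, with the mitochondrial Hspd1 and Hspe1 and the endoplasmic reticulum chaperone Serpinh1. Its median log2 difference was 0.98, with a range from 0.18 to 2.33. Hspa1a (5.01-fold) and Hspb1, the small heat shock protein HSP27 (4.46-fold), led that list, and the second Hspb1 probe set gave 2.22 on the log2 scale. Of the 27 detected NRF2 targets, which are antioxidant and glutathione genes, 24 were higher and 12 at least 2-fold higher, with a median of 0.92. Slc7a11 and Hmox1 led them, while Gstm1 (-0.20) and Tkt (-0.13), a glutathione transferase and the pentose phosphate enzyme transketolase, had the lowest values. All 28 detected targets of ATF4, the transcription factor of the integrated stress response, were higher, 10 of them by at least 2-fold, with a median of 0.85. Chac1 led that list, followed by Trib3, a pseudokinase induced by amino acid shortage, at 4.43-fold. The medians of these 3 lists exceeded those of all 10000 matched random lists, whose central 95% ran from -0.17 to 0.11 at the widest. A probe set naming the gene alone was found for 24 of 28, 28 of 30 and 28 of 30 genes of these lists, and the other genes were not analysed here.

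Inflammatory and sterol synthesis genes were lower. Of 26 detected NF-kB and inflammatory targets, 21 were lower and 13 at least 2-fold lower, with a median log2 difference of -1.004. Of these 13, Il6 was under the detection limit with celastrol (6.40 with DMSO, 5.15 with celastrol), so its fold is uncertain. Nos2 and Cxcl5 had the lowest values, and Ccl2, the monocyte chemokine, was 2.99-fold lower. Mmp13, a collagenase, and Ptgs2, the inducible cyclooxygenase, went the other way, 2.13-fold and 1.95-fold higher. Of 20 detected genes of cholesterol synthesis, 19 were lower and 9 at least 2-fold lower, with a median of -0.92. Hmgcs1 and Idi1 had the lowest values, the second Idi1 probe set gave -1.75, and Sc5d, a late-step desaturase, was the exception at 0.17. Both medians lay below those of all 10000 random lists, and 30 of 32 and 20 of 25 listed genes had a probe set naming them alone. Fatty acid synthesis genes differed less, with 12 of 15 lower, none by 2-fold, and a median of -0.27 at percentile 0.64 of random lists. Acss2, an acetyl-CoA synthetase, was 1.82-fold lower and Elovl6, a fatty acid elongase, 1.51-fold lower, while Elovl5 was 1.51-fold and Me1, malic enzyme, 1.37-fold higher. The difference between the cholesterol and the fatty acid list was not tested.

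**Figure D2:**
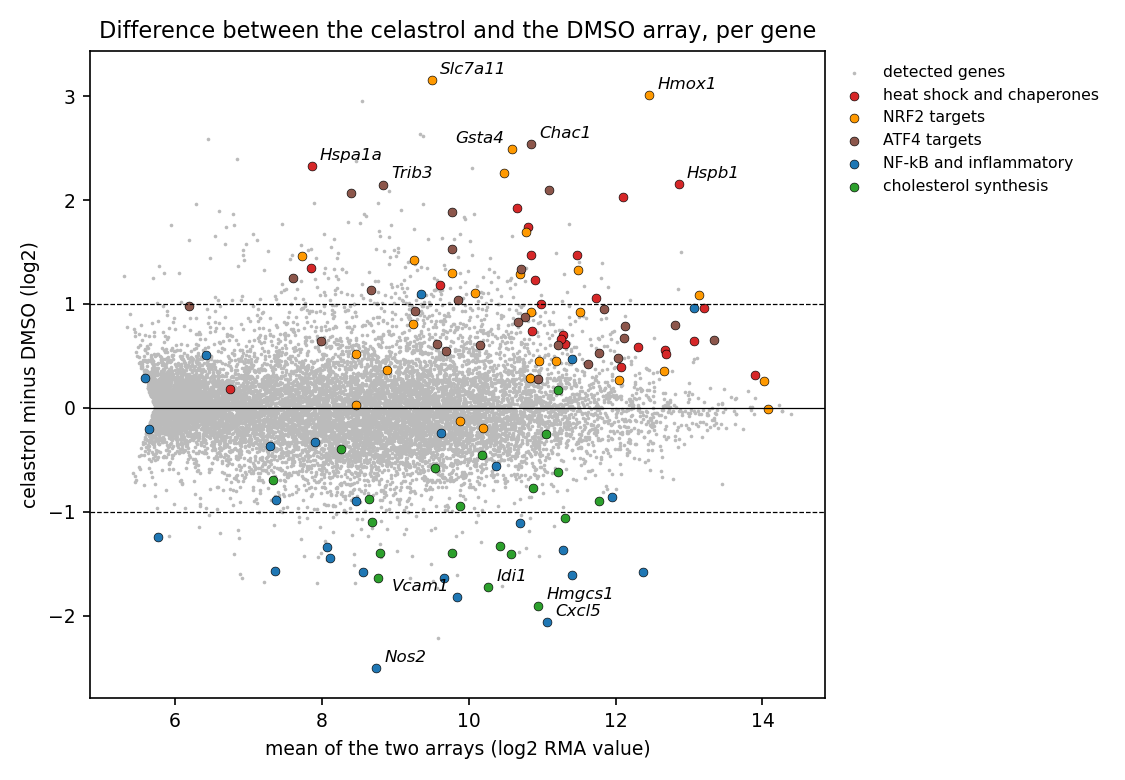
Difference between the arrays (y axis, celastrol minus DMSO on the log2 scale) against the mean of both arrays (x axis, log2 RMA value) for 13902 detected genes (grey), with the members of 5 gene lists in colour and dashed lines at 2-fold. Heat shock, NRF2 and ATF4 genes lie mostly above 0 and NF-kB and cholesterol synthesis genes mostly below.

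Immediate early genes, the transcripts that respond first to growth factors and stress, were also higher, with 25 of 29 above 0, 13 by at least 2-fold and a median of 0.74, above all random lists. Dusp4 and Dusp5 (4.24-fold), both MAP kinase phosphatases, led them, while Klf2 (-0.43) and Jun (-0.32) were lowest. The joint list of autophagy and lysosome genes had a median of 0.34, above all random lists, with 21 of 28 higher and 4 by at least 2-fold. Its lysosomal enzymes, membrane proteins and proton pump subunits were all higher. The autophagy genes were mixed, with Gabarapl1 (1.12) and Sqstm1 (1.08) higher and Atg5 (0.08), Atg7 (0.09) and Becn1 (-0.15) nearer 0. The parts were not tested separately, so the call does not describe autophagy genes as a group. Gla, the lysosomal alpha-galactosidase, was 3.35-fold higher and Atp6v1h, a subunit of the proton pump, 2.35-fold higher, while Tfeb (-0.26), which encodes a regulator of lysosomal genes, and Atg9b (-0.19) were lowest. Glycolysis and HIF1 targets had a median of 0.18 at percentile 99.5, with Slc2a1, the glucose transporter GLUT1, 2.63-fold and Bnip3, a mitophagy receptor, 2.61-fold higher, and Adm, adrenomedullin, 1.79-fold lower and Pfkfb3 at -0.26. The second Bnip3 probe set gave a smaller difference (0.88). Metal response genes had a median of 0.24 over 9 members, at percentile 98.3, led by the zinc exporter Slc30a1 (2.24-fold) and followed by metallothionein Mt1 (1.35-fold). The metal transporters Slc39a10 (-0.55) and Slc30a10 (-0.11) were the 2 lower members, and the list was not split into induced and repressed genes. The p53 targets lay at percentile 97.53 with a median of 0.13, and their members went both ways. Of 22 detected members 14 were higher, 6 by at least 2-fold, and 8 lower, 1 by at least 2-fold. Plk3, a stress kinase, and Eda2r, a death receptor family member, were 3.19-fold and 3.07-fold higher, and Fas, another death receptor, and Sesn1 were lower (-1.43 and -0.56). That call for p53 targets ended under 3 of the 8 alternatives, at a percentile of 97.1 at the lowest, and that for the metal list under the trimmed mean (94.9).

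Mitosis genes were lower by small amounts. The mitosis list had a median of -0.30, with 26 of 29 lower, at percentile 0.02. The S phase list had a median of 0.19, with 22 of 29 members higher and 7 lower, at percentile 99.7, which does not pass the limit divided by the number of lists. The contrast between these lists was not tested. No S phase gene reached 2-fold. Mcm10 (1.79-fold) and Cdt1 (1.66-fold), which act in replication origin licensing and firing, were highest, and Ccne1 (1.56-fold) and Tk1 (1.45-fold) lower. Among mitotic genes, Nusap1, a spindle protein, was 2.05-fold lower and Ccnb2, a mitotic cyclin, 1.68-fold lower, with Cenpf (1.38-fold) and Nek2 (1.37-fold) higher.

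Structural genes of fibroblasts and the respiratory chain were lower by small amounts. Extracellular matrix genes had a median of -0.24 with 23 of 27 lower, at percentile 0.03. Thbs1, thrombospondin, was 1.66-fold lower and Timp3, a metalloproteinase inhibitor, 1.56-fold lower, whereas Col6a3 was 2.09-fold higher and Col4a1 1.13-fold higher. Contractile genes and SRF or TGF-beta targets had a median of -0.24 with 20 of 29 lower, at percentile 0.17. Ccn2, connective tissue growth factor, stood at -1.43 and Myl9, a myosin light chain, at -1.38. Smad7, a feedback inhibitor of TGF-beta signalling, was just over 2-fold higher and Skil stood at 0.58. The contractile genes, SRF targets and TGF-beta targets of this list were not separated, so its median does not describe TGF-beta targets alone. Of 32 subunits of oxidative phosphorylation, 31 were lower, none by 2-fold, with a median of -0.24 at percentile 0.05. Sdhd was 1.42-fold lower, Ndufb3 1.35-fold lower, and Cox5a had the same value in both arrays within 0.01.

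Genes of endoplasmic reticulum folding showed no common direction, but differences of at least 2-fold were all upward. The median of the 28 members was -0.05, at percentile 36.6, and their mean was 0.12, of opposite sign. Of these members 12 were higher and 16 lower, with 4 at least 2-fold higher and 0 at least 2-fold lower. Dnajb9, an ER co-chaperone, and Atf6, a stress sensor of the ER membrane, were 3.30-fold and 2.40-fold higher, and Creld2 and Sdf2l1, also ER stress genes, were 1.58-fold and 1.45-fold lower. Proteasome subunits had a median of 0.10 with 26 of 32 higher, at percentile 97.4, just inside the central 95%. Psmc2 (1.47-fold) and Psmc6 (1.35-fold) were highest, and Pomp (1.14-fold) and Psmb1 (1.10-fold) were lower. Under 5 alternatives the proteasome list lay outside the central 95%.

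The PGC1 and thermogenic list had a median of 0.13, inside the random range at percentile 95.03. Its highest member was Ppargc1a, which encodes the coactivator PGC1-alpha, at 8.27 with DMSO and 9.73 with celastrol, 2.75-fold higher, and its second probe set gave 1.60 on the log2 scale. Elovl3 was under the detection limit with DMSO and at least 1.45-fold higher. Acadm, a fatty acid oxidation enzyme, was 1.62-fold lower and Pdk4 1.32-fold lower. Glucocorticoid receptor targets had a median of 0.13 at percentile 96.2, with Ddit4 (2.88-fold) and Klf9 (2.25-fold) higher and Ccl2 and Angptl4 (2.71-fold) lower. That list was not split into genes the receptor induces and genes it represses, so its median gives no direction of receptor activity. Type I interferon genes had a median of -0.01 at percentile 46.2, with 17 of 25 measured members detected. Cxcl10, an interferon-inducible chemokine, was 2.10-fold lower and Ddx58, the RNA sensor RIG-I, 1.71-fold lower, while Dhx58 (1.44-fold) and Irf9 (1.33-fold) were higher. With the stricter detection limit the interferon median became -0.35, at percentile 0.11.

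Ribosomal proteins, with a median of -0.03 over 24 members, and ribosome biogenesis genes, with a median of -0.06 over 29, lay within the random range at percentiles 43.2 and 34.2. Single ribosomal protein genes ran from -0.26 for Rpl30 and -0.23 for Rpl14 to 0.08 for Rps3 and 0.13 for Rps14, whose second probe set gave -0.05. Among biogenesis and MYC targets, Odc1, the polyamine enzyme, was 1.49-fold and Tfrc 1.19-fold higher, and Cad and Srm were 1.45-fold and 1.32-fold lower.

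None of the 6 lists of markers of other cell types lay outside the random range. Only 7 of 14 macrophage and leukocyte markers were detected. Cd68, a lysosomal protein abundant in macrophages, was 2.76-fold higher and Cd14 1.63-fold higher, while Csf1r stood near the limit at 5.99 and 6.25. Endothelial markers had a median of 0.10, with Egfl7 at -0.18, Vwf at 0.07 and Eng at 0.12. Epithelial markers had a median of 0.01, with Krt8 at -0.04, Krt18 at 0.01 and Cldn4 at -0.05. Muscle markers had a median of 0.07, with Tnnt2 at 0.87, Tnnc1 at 0.77 and Myl4 at 0.05. Adipocyte and cartilage markers had a median of 0.11, with Sox9 at 0.31, Fabp4 at 0.41 and Col2a1 at -0.03. Neural markers had a median of 0.16 over 5 members, with Nes at 0.23, Tubb3 at 0.16 and Map2 at -0.41. The macrophage list's median was 0.09.

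**Figure D3:**
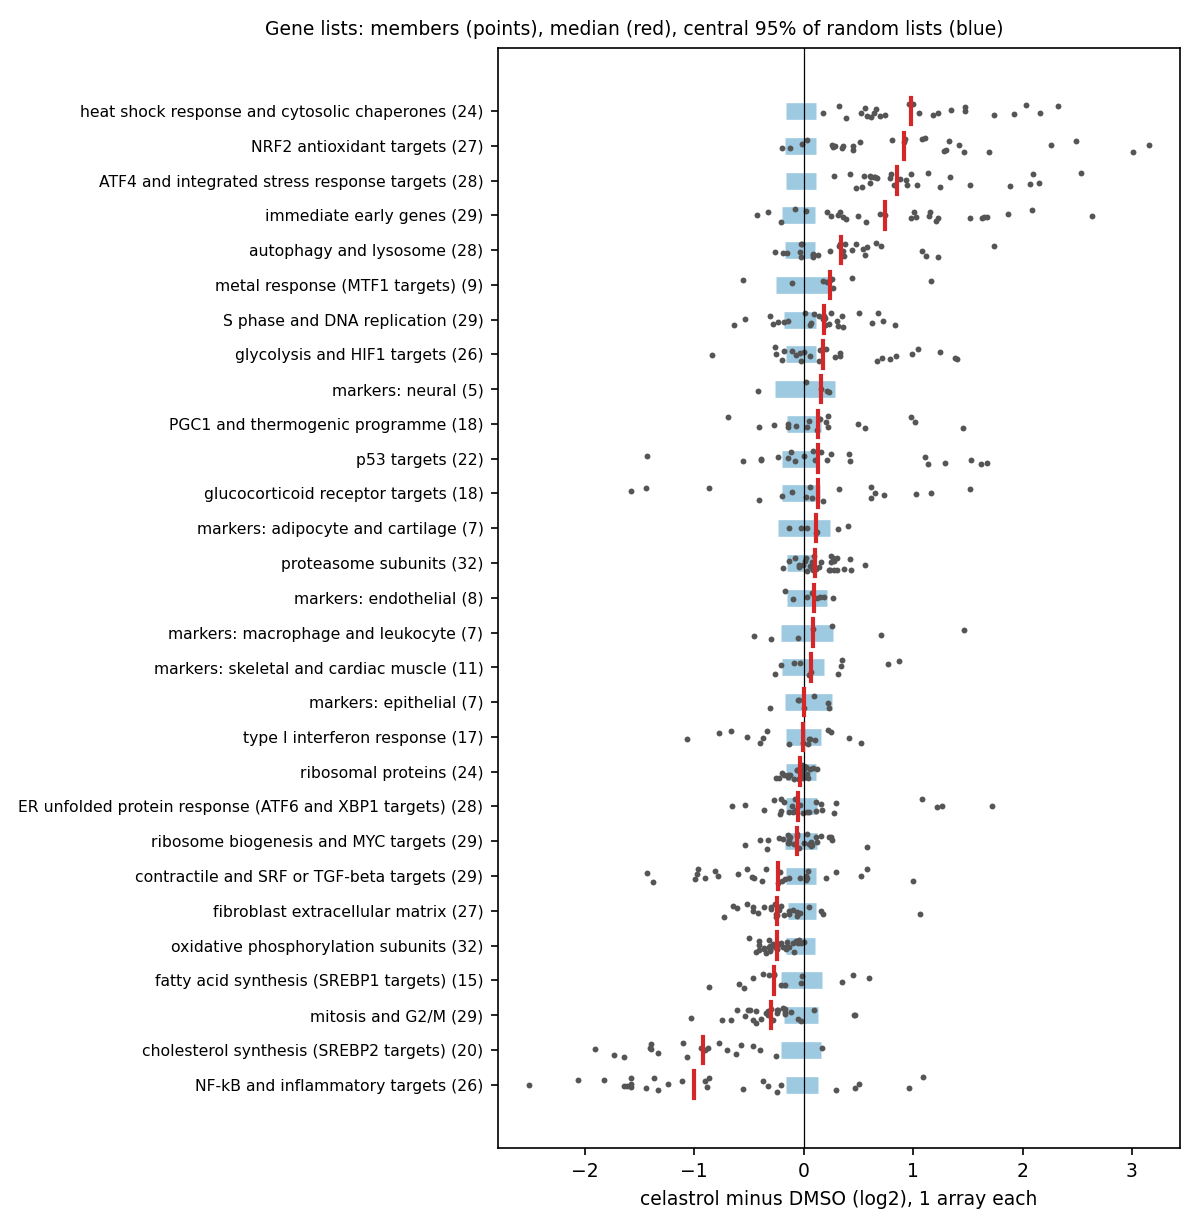
Log2 difference between the arrays (x axis, celastrol minus DMSO) of the detected members (points) of 29 gene lists (y axis, number of members in parentheses), with each list's median (red) and the central 95% of medians of 10000 random lists matched on expression (blue). The heat shock, NRF2, ATF4 and immediate early medians lie far to the right of the random range and the cholesterol and NF-kB medians far to the left.

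Of the 29 lists, 16 lay outside the central 95% of random lists, 9 higher and 7 lower, where chance gives 1.45, and more where members are co-regulated. With the limit divided by the number of lists, which does not allow for co-regulation, 10 remained. They were the heat shock, NRF2, ATF4, immediate early, and autophagy and lysosome lists upward and the NF-kB, cholesterol, mitosis, matrix and oxidative phosphorylation lists downward. All of these values compare 1 culture with 1 other, and culture, array and treatment cannot be told apart.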

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

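Of 230 recalculations of list medians, 217 kept their side of the random range and their direction where called, 4 lost a call and 9 gained one, and none reversed a called list. Medians that were not called changed sign across the alternatives for the ER (-0.07 to 0.06), interferon (-0.35 to 0.02), ribosomal protein (-0.05 to 0.01) and epithelial (-0.02 to 0.02) lists. Across all 8 alternatives the heat shock median ran from 0.97 to 1.04, NRF2 from 0.81 to 0.97, ATF4 from 0.85 to 0.99, NF-kB from -1.18 to -0.87 and cholesterol synthesis from -0.97 to -0.87. The numbers of genes changed with the fold threshold by construction, to 860 higher and 651 lower at 1.5-fold and 60 higher and 19 lower at 3-fold, while the other settings gave 257 to 302 higher and 82 to 92 lower. The proteasome list moved outside the random range with the detection limit at the median of all probe sets (0.10), no detection limit (0.10), the mean of all probe sets (0.12), quantile normalization (0.12) and the trimmed mean (0.14). The limit at the median also set apart the interferon (-0.35) and glucocorticoid (0.18) lists, for which it removed dim members. Without a detection limit the adipocyte and cartilage markers (0.21) lay outside, and with the trimmed mean the PGC1 list did (0.19). The p53 list lost its call without a detection limit, with the mean of all probe sets and with unmatched random lists (0.13 in each), and the metal list with the trimmed mean (0.23). For calls other than those tied to the threshold or to the dim members the cause was not tested. With the limit at the median, the macrophage and epithelial lists had fewer members than the 3 needed and gave no value. Of 476 recalculated gene differences, 475 moved by less than 0.20, the median absolute deviation over genes, and Bnip3 moved to 1.13 with the mean of its probe sets. Small moves were nearly fixed in advance, so they are no check on the gene values. The median difference was -0.01, the lowess trend was at most 0.06 in size, and RMA already includes quantile normalization. The mean of probe sets can change only genes that have several. Subtracting the median difference shifts every list and its random lists alike and so bears on the counts only, and subtracting the lowess trend does nearly so because the random lists are matched on expression. No paired analysis was possible because each group had 1 array, and for the same reason none could be left out. Dim genes are limited by the array's background, and values under 5.73 have no interpretable order.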

Other observations

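The tests of signal-dependent scaling, of macrophages and of short-lived transcripts were chosen after the results they bear on had been seen, while the clock and ERK lists were written down before their values were looked at. Feedback and output genes of the ERK kinase pathway formed a further list with a higher median. Among 14 feedback and output genes chosen because Dusp4, Dusp5, Hbegf and Etv5 had large positive differences, and containing none of these, 12 were higher with celastrol. Spry2 and Spry4, inhibitors of receptor tyrosine kinase signalling, were 2.54-fold and 2.28-fold higher, Phlda1 2.10-fold and Epha2, an ephrin receptor, 2.16-fold higher. Epha4 went the other way, 2.29-fold lower, and Ccnd1, cyclin D1, stood at -0.14. Their median of 0.83 exceeded those of all 10000 matched random lists, whose central 95% ran from -0.23 to 0.19. Higher ERK output in the treated culture is a candidate explanation. It was tested only at the transcript level in 1 culture per condition, and several of these genes also respond to other stress kinases, so the pathway stays open.

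The clock genes Ciart, Nr1d1 and Bhlhe41 were among the 12 largest positive differences. The prediction for cultures at different circadian phases was that output genes would be higher and genes repressed by REV-ERB, the product of Nr1d1, lower. The 7 other output genes had a median of 0.69, above all random lists, with Nr1d2 2.25-fold and Tef 2.08-fold higher and Hlf at -0.12. The 4 measured REV-ERB-repressed genes were also all higher, with a median of 0.60 at the 99.5th percentile, among them Arntl at 1.70-fold and Clock at 1.51-fold. The upper bound of random lists for these 4 genes was 0.39, so the predicted opposite directions were not seen. A phase difference need not move both groups in opposite directions at a single time point, so a phase shift remains open. The clock genes compared are few, and a general change of clock amplitude or direct induction of these repressors was not tested.

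The joint pattern of higher stress lists and lower NF-kB and cholesterol lists was set against technical accounts. A signal-dependent trend between the arrays ran only from -0.06 to 0.02 over detected genes, and after it was removed the medians were 1.02 for heat shock, 0.97 for NRF2, 0.91 for ATF4, -1.05 for NF-kB and -0.87 for cholesterol, so the smallest was 0.87 in size. This replaces a count of lists outside the random range, which was nearly fixed in advance because the random lists are matched on expression. The small trend was itself largely fixed in advance, since the quantile normalization in RMA tends to remove such trends. The values show only that no trend left in the deposited values accounts for these medians. A general loss of short-lived transcripts would lower immediate early genes, whose median was 0.74. These genes also respond to growth factors and stress, so induction could hide a loss. The value therefore cannot decide this account. Macrophages present in the DMSO culture and not in the celastrol culture would bring their abundant transcripts above background with DMSO. Of 7 such transcripts 4, Lyz2 among them, were under the detection limit in both arrays. Of the 7, 0 were both above it with DMSO and lower with celastrol beyond the receptor scatter of -0.42. These 7 were chosen after the data were seen. Fcgr3, in the planned macrophage list but not among them, did meet that criterion, at 5.76 with DMSO and 5.31 with celastrol. Its DMSO value was just over the detection limit and its celastrol value under it, so the size of that drop cannot be read. The same holds for Fcer1g, which was lower by less (-0.30). Cd68 and Cd14 were higher, so the direction of the markers decides nothing. This is the third criterion used for macrophages and was set with these values known. The second, which asked for transcripts at least 1 log2 unit above the limit, found none and left the question open. The outcome of the third was known when it was set, so it cannot decide whether macrophages contributed to the lower NF-kB list. Handling of 2 single cultures and arrays other than the compound remains open, since 1 array per group cannot tell it from celastrol.

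Probe sets outside the named genes also differed. Of 12146 without a gene name, 202 were at least 2-fold higher with celastrol and 216 at least 2-fold lower, counted without a detection limit. This is a more even split than the 262 and 92 among detected genes with a name. Without a detection limit the genes with a name gave 263 higher and 92 lower, so the limit does not account for the different split. Of 1613 naming several genes, 17 were higher and 6 lower by that measure.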
